A study of Mus musculus with 8 samples.

How the data were processed

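Total RNA from microdissected E9.5 forebrain was isolated with a PicoPure kit, checked by absorbance and capillary electrophoresis, labelled with the 3′ IVT Express kit and hybridised to whole-genome Affymetrix mouse arrays, per the labels' protocols. The 8 arrays fall into 4 wild type and 4 VEGF120 by their genotype label. The labels do not say whether each array came from a separate embryo, litter or pool, so p-values measure the spread between these arrays, which may be technical in part.

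The deposited value table holds 1 intensity per probe set and array on a linear scale, made by the authors with MAS5 in Affymetrix Expression Console, per the submitters' processing notes; versions are not given in the sources used here. The 2% trimmed mean of every array was 250 in the values, so each array had been scaled to that target. All values were above 0, and at most 0.0044% of probe sets had identical values in any pair of arrays, so all 8 were counted as separate samples. The table has no detection calls. A second deposited table holds the authors' own comparison as an unsigned fold change (ratio) with its direction and unadjusted p-values, per the file headers. It was made with PLIER summaries and quantile normalization over 3 coded groups of arrays, and lists the probe sets with p-values of at most 0.05 in an analysis of variance and in an unpaired test and a fold of at least 1.5, per the file headers. The codes were taken as wild type and VEGF120 from the heading of the deposited enrichment output; the third group is not analysed here. That table also holds 12 columns of per-array values whose names match no sample label, and these were not used. A deposited enrichment output from DAVID clusters annotation terms of the same list, and a further table repeats its folds by gene ontology term.

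Gene names came from the authors' table of 330 probe sets, since the other tables and the reference used here do not pair probe sets with genes. A probe set was named where it had 1 current symbol (251), and was left unnamed with several (13) or none (66). Entrez identifiers of 219 were found in a RefSeq gene table of assembly GRCm38.p6, which changed 27 symbols. A probe set without a name here is not without a gene. The planned fit with 1 row per gene, and camera tests of 26 gene lists fixed beforehand, would need names for all probe sets, so the fit by probe set, which was also planned, carries the comparison and the lists are described through their named members.

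Signals were taken as log2(value + 16), which understates the change of dim probe sets. The 64 control probe sets were left out, and probe sets with a mean below the 40th percentile over all 8 arrays were removed; the threshold lies at a signal of 36.9. The genotypes were compared with limma (3.58.1, in R 4.3.3; lmFit, then eBayes with an intensity trend), without a replicate block, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Dim probe sets of the deposited list were fitted without the filter. Single values were compared by two-sided exact permutation of 4 against 4. Where a gene had several named probe sets the brightest stood for it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The fit was tested on simulated arrays with 200 changed probe sets among 27022, where it made 139 calls, 5 of them false.

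The naming rule, written before the data were examined together with the gene lists, takes Vegfa and its ligand and receptor list, then in each direction up to 12 genes past the threshold whose arrays do not overlap, filled up to 8 by the smallest unadjusted p where fewer pass, and the 3 members of each list with the smallest p. Clone names were passed over. It gave the 25 genes reported; a few others are not reported here by name and were left out of the counts per gene list. Alternatives changed the added value to 1 or 64, the scaling (quantile, median), the filter (none, 60th percentile), the variance model, array weights, the replicate block and the arrays included, each array being left out in turn. Neighbouring genes were read from the RefSeq table, and none of its coordinates is given.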

Results

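Forebrain was microdissected from mouse embryos at E9.5 and its RNA was hybridised to whole-genome Affymetrix mouse arrays, 4 from wild type and 4 from VEGF120 embryos on a C57Bl/6 background. VEGF120 mice carry a knock-in that leaves VEGF120 as the sole isoform of VEGF-A, the growth factor that drives blood vessel formation; VEGF120 is the short isoform that binds heparan sulfate poorly. The comparison asks which forebrain transcripts differ when the longer isoforms are missing. Each array held 45101 probe sets, of which 64 were controls, and 27022 of the other 45037 lay above the brightness filter. The median signal of an array was 58.1 ± 1.48 (SD, n = 4) in wild type and 64.7 ± 2.68 (SD, n = 4) in VEGF120, with every VEGF120 array above every wild type array (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give, 0.172 after Benjamini-Hochberg adjustment over 6 array measures). The small number of arrays limits the precision of every value below.

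Among named genes the smallest p belonged to Spry2, at lower signal in VEGF120. Spry2, a feedback inhibitor of fibroblast growth factor (FGF) and other receptor tyrosine kinase signalling, was measured at 9.84 ± 0.39 in wild type and 8.81 ± 0.15 in VEGF120 (log2 signal, SD, n = 4 each), a difference of −1.03 ± 0.17 (SE) or 2.04-fold. Sp8, a zinc finger transcription factor of the anterior forebrain, differed by −0.66 ± 0.16. In the opposite direction, the homeobox factors Prrx1 and Six2, which mark head mesenchyme, differed by 0.76 ± 0.16 and 0.70 ± 0.16, and the glycolytic enzyme Pfkl by 0.68 ± 0.13. None of these differences passed adjustment over all probe sets: limma called 0 probe sets at an adjusted p under 0.05, 0 higher and 0 lower, and the smallest adjusted p was 0.465. The methods' unpaired test, run here on the MAS5 signals with the same filter and adjustment, also called 0. This is not the study's own selection, which used PLIER summaries and unadjusted p-values. Limma called 1 probe set, of Bak1, without VEGF120 replicate 1, so every gene below is described by its values only.

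Without adjustment, 2638 of the 27022 probe sets had a limma p under 0.05, 1714 of them higher and 924 lower in VEGF120. Chance gives 1351 on average, but the count varies widely between groupings of the arrays. Of 35 splits of the 8 arrays into 4 and 4, the genotypes included, 3 gave at least 2638, so chance cannot be excluded for this count. Without wild type replicate 3 the count was 1653, with 510 lower, and without wild type replicate 4 the lower part was 502. The 4 arrays of one genotype lay entirely beyond the 4 of the other for 1351 probe sets, 5.0% of those tested, where chance gives 2.86% on average. The spread of that share over other splits was not tested. Of the probe sets at an unadjusted p under 0.05 the share higher in VEGF120 was 65.0% of 2638 on the deposited scaling, 50.5% of 2306 after quantile normalization and 16.3% of 3701 after centring each array on its median, which removes a difference of 0.12 (log2) between genotypes in the array medians. The median difference of the tested probe sets was smaller, at 0.0407, so centring lowers every probe set by more than that typical difference. Which direction prevailed thus rested on the scaling. On simulated arrays of the same size, 73.1% of probe sets changed 2-fold and 34.3% of those changed 1.5-fold were recovered among 27022. That simulation planted 200 changes of 1.5-, 2- or 3-fold and drew independent noise for each probe set. Its shares therefore do not tell how many changes of that size this comparison could find.

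Gene names were at hand for the probe sets of the authors' deposited comparison, which lists 330 probe sets, 139 higher and 191 lower in VEGF120, and Vegfa is not among them; Vegfa is not analysed here. Of the 330, 251 carried a single current symbol, standing for 247 genes, and 120 lay above the brightness filter. In these MAS5 signals 118 of the 120 bright probe sets had the direction of the authors' deposited table, and 79 had an unadjusted limma p under 0.05, all 79 in that direction, 23 higher and 56 lower. Of the 210 dim ones 162 had that direction and 31 had an unadjusted p under 0.05. With adjustment over the list alone 44 of the 330 passed, 39 of them bright, against 0 over all probe sets. The list was chosen on these samples, so neither its direction nor that count is independent evidence.

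**Figure D1:**
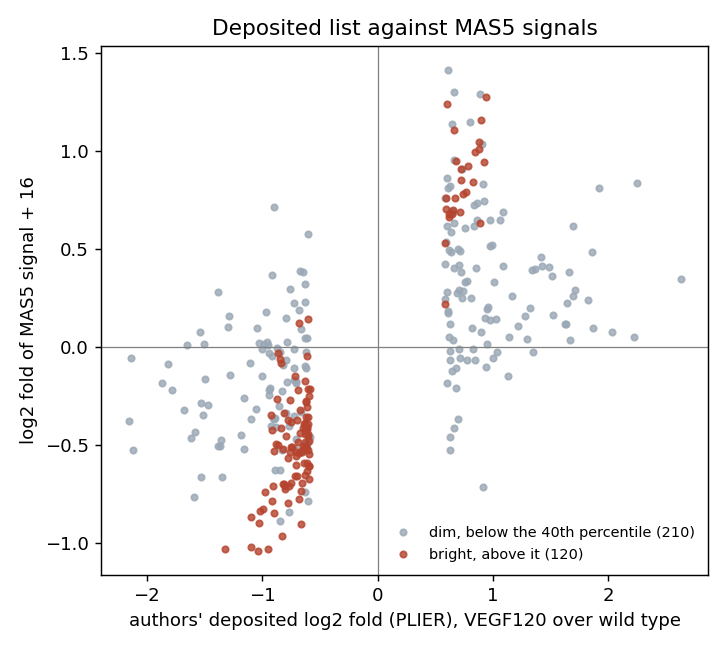
Log2 fold of VEGF120 over wild type in the authors' deposited table (horizontal, from PLIER summaries) against the log2 fold of MAS5 signal + 16 (vertical), with 1 point per probe set of the 330 listed. The 120 bright probe sets lie in the same direction on both axes in 118 cases, and the 210 dim ones in 162 cases.

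Arrays did not overlap for 14 bright named genes lower in VEGF120 and 8 higher. Among those with the smallest p, the lower ones reported were Spry2, Phyhipl, Ndnf, Cap1, Sp8, Ggct and Lin7c. Phyhipl differed by −1.04 ± 0.20 (SE), and Ndnf, a secreted factor named for its action on neurons, by −0.84 ± 0.17. Cap1, an actin-binding protein, differed by −0.70 ± 0.17, Lin7c, a scaffold protein of cell junctions, by −0.54 ± 0.15, and Ggct, an enzyme of glutathione breakdown, by −0.51 ± 0.14. The authors' deposited table also lists a second Spry2 probe set, lower by 1.82-fold there, against 1.93-fold for the first. In MAS5 signal the second differed by −0.03 ± 0.29, so the probe sets of Spry2 disagreed in these signals but not in that table. The 8 higher ones were Pfkl, Prrx1, Six2, Creb3l4, Dlx1, Pdk1, Vmac and Rnf10. Creb3l4, a membrane-bound transcription factor of the CREB family, differed by 1.24 ± 0.29, Rnf10 by 0.95 ± 0.33 and Vmac by 0.91 ± 0.27. Creb3l4 and Rnf10 lie at the edge of the brightness filter, and their differences were 1.86 and 1.51 with 1 added to the signal in place of 16, and 0.64 and 0.48 with 64 added; Vmac fell to 0.56 and Dlx1 to 0.51 with 64 added. These 15 genes were picked for arrays that do not overlap, which fixes the exact permutation p at its smallest value, 0.0286, so that p is no evidence. Their adjusted p was 0.465 to 0.483 in limma. Centring the arrays on their medians lowers each difference by 0.12, which is less than any of the 8 higher ones, so it could turn none of the 15.

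**Figure D2:**
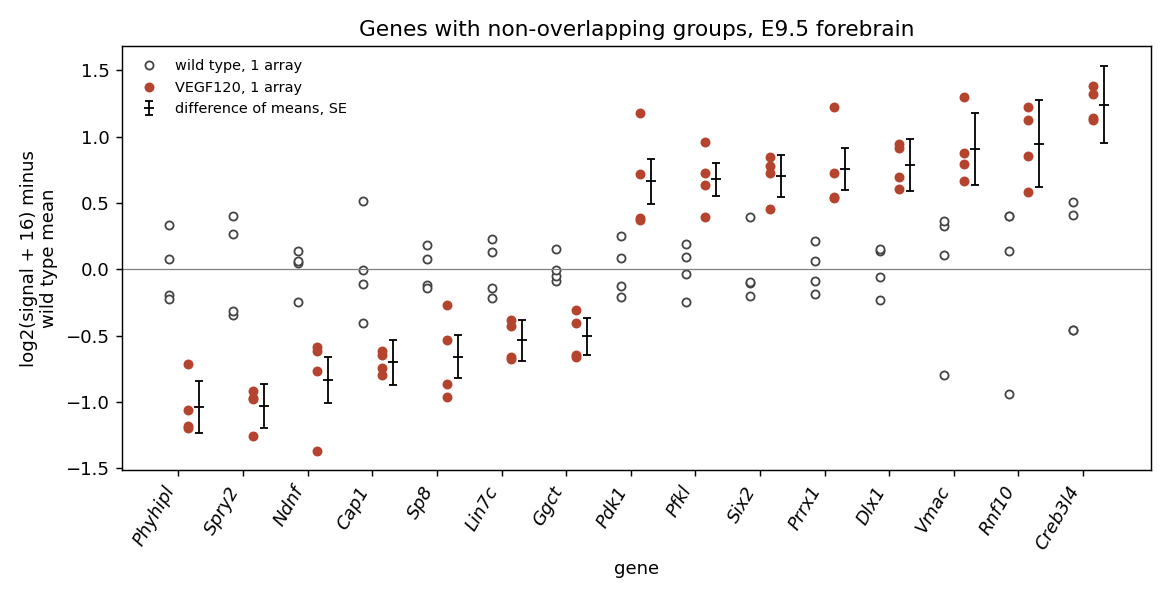
Log2(signal + 16) of each array minus the wild type mean (vertical) for 15 genes (horizontal) among those with the smallest p of the named genes whose groups did not overlap, with open points for the 4 wild type and filled points for the 4 VEGF120 arrays and a bar for the difference of means ± SE. With 16 added, differences run from −1.04 for Phyhipl to 1.24 for Creb3l4.

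The gene lists fixed beforehand could be described only through the members that the deposited table names, 17 genes from 12 of the 26 lists, and no list reached the 5 bright members set for a test. All of these members were picked by the study on these samples, by p-values of at most 0.05 and a fold of at least 1.5, and a count adjusted over the list alone takes in only the bright named members, since the other members were not tested. Passing was thus largely fixed by that selection, and neither these counts nor the directions are independent evidence. In the list of neural crest and head mesenchyme genes 3 of 33 members are reported and all 3 were higher, with a median log2 difference of 0.76. Besides Prrx1 and Six2 this was Alx1, a homeobox gene of the mesenchyme around the forming face, at 1.045 ± 0.245 (SE) with overlapping arrays. Adjusted over the list alone, here 3 p-values, 3 of 3 passed, and 0 over all probe sets.

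In the list of forebrain patterning genes 4 of 49 members were named, 1 higher and 3 lower. Dlx1, a homeobox gene of ventral forebrain neurons, differed by 0.79 ± 0.20 (SE), with 6.07 ± 0.18 in wild type and 6.86 ± 0.17 in VEGF120 (SD, n = 4 each). Fgf18, an FGF ligand, differed by −0.87 ± 0.36, by −0.49 with 64 added to the signal and by −0.44 without VEGF120 replicate 3, which read 4.605 against 5.953 to 6.53 on the other VEGF120 arrays. Pax3, a factor of the dorsal neural tube and neural crest, differed by −0.48 ± 0.22, and both had overlapping arrays; Pax3 falls outside the naming rule and completes the count. Adjusted over the list alone, here 4 p-values, 4 of 4 passed, and 0 over all probe sets, but Fgf18 and Pax3 lost this under alternatives: Fgf18 passed in 12 of 19 that tested it and Pax3 in 12 of 20. Neither passed without wild type replicate 1, 2 or 3 or VEGF120 replicate 1 or 3, without the intensity trend, or in the methods' unpaired test. Pax3 also failed without wild type replicate 4.

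Single named members stood for each of the remaining lists. Pfkl was the one glycolysis gene, and Pdk1, which restrains the use of pyruvate inside mitochondria, the one gene of the hypoxia response list, at 0.66 ± 0.17 (SE). Suz12, a subunit of Polycomb repressive complex 2, differed by 1.11 ± 0.44 and the Notch ligand Jag2 by 0.53 ± 0.22, and with 64 added by 0.60 and 0.33; Suz12 lies at the edge of the brightness filter. Sfrp1, a secreted Wnt antagonist, differed by −0.59 ± 0.17, and Bcl2l11, a pro-apoptotic member of the Bcl-2 family, by −0.69 ± 0.21; the arrays of these 4 genes overlapped. Adjusted over the list alone, which for 1 named member is the unadjusted p of a gene selected for a low p, these 6 genes were under 0.05, and over all probe sets 0 were. The p of Jag2 was 0.0336 and that of Suz12 0.0254, and under alternatives Jag2 passed in 10 of 19 that tested it, failing after quantile normalization or median centring, without the brightness filter, with the replicate block, without both replicates numbered 4 and without wild type replicate 1 or 4 or VEGF120 replicate 1 or 4. Suz12 passed in 11 of 14, failing without wild type replicate 1 or 4 and in the methods' unpaired test. Lin28a, from the neural progenitor list, differed by −0.08 ± 0.16, within the spread between arrays. Its probe set was bright, yet the authors' deposited table lists it as 1.78-fold lower, so the size of its change differed between the MAS5 and PLIER summaries. Vcan, Top2a and Tyms, from the lists of extracellular matrix, mitosis and DNA replication genes, were dim, at 0.07 ± 0.17, 0.10 ± 0.14 and 0.59 ± 0.41, and at 0.39, 0.46 and 1.499 with 1 added in place of 16. Single arrays moved these values: Tyms was at 0.956 without wild type replicate 4 and 0.908 without VEGF120 replicate 4, Vcan at 0.172 without wild type replicate 3 and 0.0079 without wild type replicate 4, and Top2a at 0.0628 without VEGF120 replicate 1. The arrays of Top2a did not overlap, and the authors' deposited table gives it a 3.65-fold increase. Its probe set lay at percentile 0.76 of brightness, with log2 signals of 4.16 to 4.38, so separation this close to the floor says little about Top2a. No member of the lists for VEGF ligands and receptors, endothelium, tip cells, pericytes, macrophages, erythroid cells, surface ectoderm, neuronal differentiation, axon guidance, endoplasmic reticulum stress, immediate early genes, oxidative phosphorylation, ribosomal proteins or sex-linked genes was named, and these are not analysed here.

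The authors' deposited enrichment output groups the listed probe sets into term clusters. Its leading cluster, of proteins with EGF-like domains, has a score of 3.33 and 12 probe sets, of which 9 were dim and 3 bright in the MAS5 signals. The bright ones were Jag2, Dlk1, a Notch-related membrane protein, at 0.84 ± 0.20 (SE), and Matn2, a matrix protein, at −0.46 ± 0.28. The second cluster, of negative regulators of transcription, has a score of 3.26 and 20 probe sets. Of these 14 were bright, 7 higher and 7 lower. An unadjusted limma p under 0.05 was found for 12 of the 14, against 79 of all 120 bright listed probe sets. All were selected for a low p on these samples, so that count is no independent evidence. Dlk1 and Matn2 were chosen after their values were seen, to complete the count of 3.

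The ratio of 3′ to 5′ control signals, a measure of RNA integrity and labelling length, did not separate the genotypes by more than the spread between arrays when all 8 were used. For β-actin the log2 difference was 0.36 ± 0.05 in wild type and 0.46 ± 0.16 in VEGF120 (SD, n = 4 each; two-sided exact permutation p = 0.286), and the difference between genotypes fell from 0.0998 to 0.0236 without VEGF120 replicate 4. For Gapdh it was −0.32 ± 0.04 and −0.23 ± 0.13 (exact permutation p = 0.143), but without VEGF120 replicate 1 the genotypes differed by 0.131 (exact permutation p = 0.0286). Without VEGF120 replicate 4 the Gapdh difference shrank, as that of β-actin did. VEGF120 replicate 4 had the highest ratio for both, 0.69 and −0.04. Correlation between arrays across probe sets, which are not independent replicates, averaged 0.972 within wild type, 0.963 within VEGF120 and 0.965 between genotypes. The first principal component, with 23.9% of the variance, ran from −36.5 to −1.8 in wild type and from 1.5 to 43.9 in VEGF120. Its exact permutation p was 0.0286, unadjusted and the smallest that 4 against 4 can give. Wild type replicates 1 and 2, at −3.88 and −1.84, lay close to VEGF120 replicate 2, at 1.51.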

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

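Of 64 groups of 4 arrays examined, for the 25 named genes and 7 array measures, 3 held an array far from the other 3, where chance gives about 3.2. The 18S ribosomal RNA 5′ control read 1047 on wild type replicate 4 and between 9454 and 11131 on the other wild type arrays. Bcl2l11 read 7.30 on VEGF120 replicate 1 (log2 signal) and between 6.46 and 6.52 on the other VEGF120 arrays. Lin28a read 8.67 on wild type replicate 1 and between 8.30 and 8.34 on the other wild type arrays.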

How the results depend on the processing

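The alternatives for the counts at an unadjusted p, for passing over a list alone, for the overlap with the deposited table and for RNA quality, most of those for the count of probe sets past the threshold, the run without both replicates numbered 4 and the methods' unpaired test were chosen after seeing the data. Over 20 alternatives limma and that test called 0 probe sets past the adjusted threshold, except that 1 was called without VEGF120 replicate 1 (range 0 to 1 over arrays left out), so genes higher ranged from 0 to 1. The Gapdh 3′ to 5′ difference ranged from 0.0348 (without VEGF120 replicate 4) to 0.131 with an array left out, and at 0.131, without VEGF120 replicate 1, its exact permutation p was 0.0286. The count at an unadjusted p under 0.05 ranged from 1610 to 3701 over the alternatives and, with 1 array left out, from 1653 (without wild type replicate 3) to 3237 (without VEGF120 replicate 1), its lower part from 502 (without wild type replicate 4; 510 without wild type replicate 3) to 1285. Without both replicates numbered 4 it was 1610, with 1126 higher and 484 lower. Median centring gave 602 higher and 3099 lower (3701 in all), the 60th percentile filter 1137 higher, with fewer probe sets tested; the cause of the other shifts was not tested. The overlap in direction stayed between 271 and 284 of 330. Listed probe sets at an unadjusted p under 0.05 in the deposited direction, 79 in the main fit, ranged from 52 to 102. The highest count came without the brightness filter, which lets in dim probe sets. The replicate numbers pair no arrays by the labels: same-numbered arrays correlated over 0.1 in their deviations in 1 of 4 pairs, and with the replicate block 2358 probe sets had an unadjusted p under 0.05 and 0 passed the adjusted threshold; over its list alone Jag2 no longer passed (p = 0.0537). Of 500 values of named genes under alternatives 495 kept their direction; the others were dim or near 0, Vcan at −0.0488 and Top2a at −0.0277 after median centring, Vcan at −0.00317 without both replicates numbered 4, and Lin28a at 0.00566 without wild type replicate 1 and 0.0219 without VEGF120 replicate 2 (−0.193 to 0.0219 over arrays left out). The filter, the variance model, the replicate block and the methods' unpaired test leave a difference of means unchanged, so direction was kept there by construction. Leaving arrays out could not turn the genes picked for arrays that do not overlap. The count of 495 was thus largely fixed in advance and is no measure of robustness. The mean of all probe sets of a gene, camera and fry were not run, because they need gene names for all probe sets. Signals near background limit the dim probe sets, whose differences the added 16 flattens.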

Other observations

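The tests of dim probe sets by direction, of homeobox genes, of head mesenchyme genes against each other and against the FGF group (first seen on a wider set of genes) and of the count past the adjusted threshold were chosen only after the result was seen. Of 9 bright probe sets in the authors' homeobox term cluster 7 were higher in VEGF120, among them Prrx1, Six2, Alx1, Dlx1 and Cux1, against 21 of the other 111 bright probe sets (Fisher's exact test, two-sided p = 0.000502); Pax3 was among those lower. The cluster was picked out after this count was seen, from probe sets that the study selected on these samples, so the test decides nothing and the count is given as a description; the list of head mesenchyme genes shares Prrx1, Six2 and Alx1 with it.

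Bak1, a pro-apoptotic relative of Bcl-2, singled out after its values were seen, was the gene called without VEGF120 replicate 1. It read 7.20 on that array, 8.35 to 8.77 on the other VEGF120 arrays and 7.15 to 7.37 in wild type, and its difference moved from 1.00 to 1.34 with an adjusted p of 0.0353 in limma, where the smallest adjusted p of any probe set ranged from 0.0353 to 0.833 over the alternatives.

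Of the 35 ways to split the 8 arrays into 4 and 4, 3 gave at least the 2638 probe sets at an unadjusted p under 0.05 that the genotypes gave, and the highest other split gave 2764, so chance cannot be excluded for that count. For the 0 probe sets past the adjusted threshold no split can give fewer, so that all 35 gave at least as many says nothing about chance; the highest other gave 11.

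The 3 reported head mesenchyme genes, of 33 in their list, were higher in VEGF120, and 4 genes tied to FGF signalling (Spry2, Il17rd, Sp8 and Fgf18) were lower, none past adjustment over all probe sets. This FGF group is no list fixed beforehand but was put together from genes seen to be lower, and a second Spry2 probe set differed by −0.03 ± 0.29 (SE). A candidate explanation is that the VEGF120 dissections held more head mesenchyme. If the amount of mesenchyme also varied between arrays of a genotype, Prrx1, Alx1 and Six2 would move together inside it. The mean pairwise correlation of their residuals from the group means was 0.509. That value lay above the 95th percentile of 0.457 over 10000 random sets of 3 bright probe sets. Without wild type replicate 2 it was 0.095, without wild type replicate 1 0.41 and without wild type replicate 3 0.487, each below the matching percentile of 0.501, 0.502 and 0.5, the last by little; without any 1 of the other 5 arrays it was 0.526 to 0.685 and above it. The result depends on which array is left out. Residuals have the group means removed, so an equal excess of mesenchyme in all VEGF120 arrays would leave no such correlation. A correlation could also arise without any excess. The explanation therefore stays undecided. If mesenchyme displaced neural tissue, the FGF group should fall as the mesenchyme group rises; the residual scores gave r = −0.643 (exact permutation within genotypes, p = 0.0625) and rho = −0.524 (exact permutation p = 0.22), and r = 0.0791 without the 2 arrays farthest from the median, so that relation rests on those arrays and stays undecided. An effect of the genotype on mesenchyme or on FGF signalling stays open and untested, and levels of other abundant mesenchyme transcripts are not analysed here.

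The deposited folds were larger at dim probe sets, with a median of 1.84 below the brightness filter and 1.62 above it, and the largest fold was 6.18 below and 2.50 above. Direction was kept less often at low signal: 77.1% of dim probe sets had the deposited direction in the MAS5 values against 98.3% of bright ones (Fisher's exact test, p = 1.38e-08). This compares direction between MAS5 and PLIER summaries and does not measure the size of the deposited folds. Whether noise at low signal accounts for part of the larger folds stays open. The added 16 flattens dim differences in the MAS5 values but has no part in the deposited folds, so the shares with another added value do not bear on the size of those folds. With 1 added, 52.4% of dim probe sets reached 1.5-fold in the deposited direction against 56.7% of bright ones (Fisher's exact test, p = 0.492), and with 16 added 18.6% against 48.3%.

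Among the probe sets with the smallest p were 2 annotated to Dynlt1 and near-identical copies of it on chromosome 17, at −0.69 ± 0.12 and −0.79 ± 0.17 (SE), and the list holds 2 more for Tmem181a and its copies, at −0.27 ± 0.18 and −0.35 ± 0.26. The copies of both genes alternate along the chromosome in the RefSeq table. A shared change of these loci, such as a copy number difference, might lower all 4, yet their lowest pairwise correlation over the 8 arrays was 0.169 (0.949 for the pair of Dynlt1, 0.436 for that of Tmem181a) and the mean correlation of residuals inside genotypes 0.157, which neither meets nor excludes that prediction. Passenger sequence around Vegfa, also on chromosome 17, might enrich the list for that chromosome. Of 201 matched genes 12 lay there, an odds ratio of 1.25 against protein-coding genes (95% interval 0.633 to 2.25, Fisher's exact test, p = 0.409). Such sequence lies next to Vegfa, so a count over the whole chromosome can neither show nor exclude it. The distance of the Dynlt1 and Tmem181a copies from Vegfa is not given here. Signal shared between the copies and an effect of the genotype stay open and untested.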
